A study of Homo sapiens with 60 samples.

How the data were processed

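RNA was sequenced from SH-SY5Y cells, a human neuroblastoma line that can be differentiated towards a neuron-like state, collected at days 6, 9, 12, 15 and 18 of differentiation after exposure to lead (Pb) at 0, 0.16, 1.26 or 10 µM from day 5 onward. Per the labels, cells at passage 39 were plated in 15 cm dishes, 1 dish per replicate, and 3 dishes were collected for each day and dose, which gave 20 groups and 60 libraries. Libraries were made with PlexWell, a plate-based method in which tagmentation adds a well-specific barcode to the cDNA of each well before wells are pooled. The library names in the labels fall into 2 pools, 1 with all libraries of days 6 to 15 and 1 with all libraries of day 18.

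The authors deposited 1 table of counts per 1e+06 assigned reads (CPM) with 37334 genes and 60 columns, 1 per library, as the file name states. The submitters' processing notes name FastQC, MultiQC, STAR and featureCounts and the genome build GRCh38, without versions or settings, and the annotation, strand setting and handling of duplicate reads were not stated. Every column summed to 1e+06, and every value was a whole multiple of the value of 1 read within 0.01 read, with a largest deviation of 0.00017 read, so whole reads were recovered and no further scaling between libraries had been applied. Library totals ran from 16594259 to 50539599 reads assigned to genes. In a single library 3 reads corresponded to between 0.0594 and 0.181 CPM. This floor was used to describe low values and not as a filter. It covers counting error only because the reads carry no molecular identifiers.

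Genes with at least 1 CPM in at least 3 libraries were kept, which left 15263 genes, and 8794 genes had no read in any library. Values were analysed as log2(CPM + 1) without rescaling. A linear model with 1 mean per group was fitted to all 60 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance and 40 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the genes kept, with a threshold of 0.05. All tests were two-sided. Tested contrasts were days 9, 12, 15 and 18 against day 6 without Pb, each dose against 0 µM within each of the 5 days (15 contrasts), each dose against 0 µM as the mean of the 5 within-day differences, the mean within-day slope over dose steps 0 to 3 (doses were spaced about 8-fold), and moderated F tests of Pb by day, with 12 contrasts for all doses and 4 for 10 µM alone. Errors beside log2 changes are standard errors of the model, and errors beside CPM values are standard deviations over 3 libraries. Replicates are the dishes numbered in the labels, and the p-values measure the spread between these dishes of 1 cell line at 1 passage.

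Gene lists (28), the comparisons and their tests, the rule for naming genes and the first group of alternatives given here were chosen before the data were examined. The lists were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each contrast, for lists with at least 5 genes kept, and again with an estimated correlation. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. For differentiation, the Pb means over days and the dose trend, the genes named were the 8 largest rises and 8 largest falls among genes past the threshold with at least 5 CPM in 1 of the groups, with no overlap between the libraries of the 2 groups (differentiation) or with 1 sign at all 5 days (Pb). For each dose at each day they were up to 3 rises and 3 falls with the smallest p, or the 3 genes with the smallest p where none passed, and for each test of Pb by day the 4 genes with the smallest p. For each list described, up to 4 members with the smallest p were named. Symbols without a gene name were passed over, and XIST and Y-linked genes were not named. The similarity of the Pb differences between days was the mean Pearson correlation across genes over 10 pairs of days, with an exact permutation of the 6 libraries within each day in all ways. Gene positions are those of the RefSeq annotation of GRCh38, in which 36621 of the 37334 symbols were found.

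The first group of alternatives held a pseudocount of 0.25, no filter on low values, median-ratio rescaling of each library, a fit of only the groups compared, a block for the replicate number, edgeR 4.0.16 quasi-likelihood tests on the recovered reads, leaving out day 18, a dose scale linear in µM, and leaving out each replicate in turn. Alternatives added after the data were seen were leaving out the 2 libraries with the lowest values of long transcripts and a correction of each library for GC content and transcript length with splines of 4 degrees of freedom, for the 14843 kept genes with a reference transcript. The model was tested on simulated data built from these libraries, with all 60 simulated libraries in the fit. In a comparison of 3 against 3 of them it recovered 67.2% of genes changed by 0.5 on the log2 scale. It recovered 98.5% of those changed by 1 and 100% of those changed by 2, with 9 of 15063 unchanged genes called. As the mean over days it recovered 97% of genes changed by 0.5. Simulated reads were drawn independently for each gene, without shifts of a whole library. Splits of the real day 18 libraries other than the real one called up to 932, 1434 and 982 genes at 0.16, 1.26 and 10 µM. The simulated error rate hence need not hold for these data. Replicate libraries differed by more than counting error in each of 60 pairs (chi-square per degree of freedom from 4.51 to 45.3), so no library is a copy of another of its group. The alignment and counting of reads could not be repeated, since only the table was used here.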

Results

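In all, 60 libraries were sequenced from differentiating SH-SY5Y cells, with 3 replicate dishes in each of 20 groups formed by 5 days and 4 Pb doses. The depth per library ran from 17.3 to 34 M reads (M stands for 1e+06) at day 6, from 16.6 to 37 M at day 9, from 20.3 to 50.5 M at day 12, from 23.8 to 47.2 M at day 15 and from 16.6 to 43.3 M at day 18. The first principal component of the 60 libraries held 58.6% of the variance and the second 16.8%. In 2 libraries, the levels fell with transcript length more than in all others. Relative to the mean of their day, log2 values changed by -0.503 per log10 of length in replicate 1 of day 18 without Pb and by -0.462 in replicate 3 of day 6 with 10 µM Pb, and the next lowest slope was -0.191. All libraries of day 18 belong to another library pool than those of the other days. Differences between day 18 and day 6 hence cannot be told apart from differences between pools, whereas Pb and 0 µM were compared within each day and hence within 1 pool.

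The time course without Pb shows which genes change as the cells differentiate. By day 9, few genes had moved, and genes of the catecholamine-producing state were lower. DDC, the enzyme that forms dopamine and serotonin, went from 68.0 ± 1.84 CPM (SD, n = 3) at day 6 to 33.8 ± 1.98 CPM at day 9, and NEFM, a neurofilament subunit, from 303.7 ± 8.59 to 165.8 ± 6.63 CPM. In the noradrenergic and catecholamine list, 6 of 18 members fell and 1 rose (8 and 2 when adjusted over the list alone), and the list was lower than other genes (adjusted p = 4.89e-08). Among these, the noradrenaline transporter SLC6A2 changed by -0.96 ± 0.078 on the log2 scale (SE, adjusted p = 1.06e-12). In the neuronal cytoskeleton list 4 of 18 members fell (4 adjusted over the list alone; adjusted p = 0.000404). Among these, NEFL changed by -0.62 ± 0.057.

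Heat shock genes and p53 targets were higher at day 9 than at day 6. Of 17 heat shock genes 7 rose (10 adjusted over the list alone; adjusted p = 2.53e-08), with the small chaperone HSPB1 up by 0.40 ± 0.066 on the log2 scale. Of 20 p53 target genes 3 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 5.53e-07), led by GDF15, a secreted stress-induced member of the TGF-beta family, with a log2 change of 1.18 ± 0.11, and by the cell cycle inhibitor CDKN1A with 0.64 ± 0.080. Of 27 hypoxia and glycolysis genes 7 fell and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 5.53e-07). Among these, the lactate dehydrogenase LDHA changed by -0.25 ± 0.050. In all, 785 of 15263 genes passed, 402 higher and 383 lower at day 9. The count was 475 without replicate 1 of day 6, 506 without replicate 2 of day 6, 481 without replicate 2 of day 9, and 422 when only the libraries at 0 µM were fitted.

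At day 12 the transcriptome had shifted widely. ECEL1 (chromosome 2, 232479827 to 232487834), a neuronal peptidase of the endothelin-converting enzyme family, rose from 7.34 ± 0.517 CPM at day 6 to 1523 ± 409 CPM at day 12 (log2 change 7.48 ± 0.26, adjusted p = 4.77e-29). TFPI2 (chromosome 7, 93885396 to 93890753), a secreted protease inhibitor, rose from 24.3 ± 0.029 to 1042 ± 75.4 CPM (log2 change 5.36 ± 0.076, adjusted p = 2.05e-44). ID3 (chromosome 1, 23557926 to 23559501), which blocks DNA binding by differentiation-promoting transcription factors, fell from 272.2 ± 14.5 to 41.5 ± 1.79 CPM (log2 change -2.68 ± 0.088, adjusted p = 1e-29), and its relative ID1 fell by 2.64 on the log2 scale (SE 0.099).

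Genes of the unfolded protein response and of cholesterol and fatty acid synthesis rose at day 12. All 20 measured members of the unfolded protein response list rose (20 adjusted over the list alone; adjusted p = 2.08e-34). HSPA5 (chromosome 9, 125234853 to 125241343), the main chaperone of the endoplasmic reticulum, went from 305.4 ± 5.96 to 2002 ± 24.9 CPM, and the disulfide isomerase PDIA4 changed by 2.54 ± 0.046 on the log2 scale. Of 27 cholesterol and fatty acid synthesis genes 26 rose (27 adjusted over the list alone; adjusted p = 8.27e-35), with DHCR7, which catalyses the last step of cholesterol synthesis, at 2.64 ± 0.056. Of 24 NRF2 targets, genes of the antioxidant defence, 15 rose and 1 fell (15 and 1 adjusted over the list alone; adjusted p = 4.77e-09), with NQO1, a quinone reductase, at 2.60 ± 0.11.

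Cell cycle genes were lower and immediate early genes higher at day 12. Of 30 cell cycle and replication genes 29 fell (30 adjusted over the list alone; adjusted p = 5.02e-14). Among these, MCM5, a subunit of the replicative helicase, went from 243.2 ± 11 to 76.4 ± 2.09 CPM. Of 21 immediate early and cAMP response genes 16 rose and 3 fell (16 and 3 adjusted over the list alone; adjusted p = 2.09e-09), with the cAMP-responsive factor CREM at 2.73 ± 0.075. Of 12 cholinergic markers 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.00312). Among these, acetylcholinesterase, ACHE, changed by 1.39 ± 0.066. Of 8 Schwann and glial markers 6 rose (6 adjusted over the list alone; adjusted p = 9.97e-05), among them GAP43, which neurons also express. Of 20 mesenchymal markers 12 rose and 5 fell (12 and 5 adjusted over the list alone; adjusted p = 0.0316), and the adjusted p = 0.103 with an estimated correlation. The call of this list also ended after rescaling. Of 32 cytosolic ribosomal protein genes 31 fell (31 adjusted over the list alone; adjusted p = 1.09e-11), and the adjusted p = 0.211 with an estimated correlation.

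In total 8583 genes passed at day 12, 3300 higher and 5283 lower. The median of all genes was -0.107 as deposited and -0.007 after median-ratio rescaling, and the share of higher genes moved from 38.4% to 51.4%.

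By days 15 and 18 genes of neuronal structure and transmission were higher than at day 6. GAP43, a growth cone protein, rose from 125.3 ± 2.09 CPM at day 6 to 768.5 ± 48 CPM at day 18 (log2 change 2.61 ± 0.048, adjusted p = 6.24e-40), and NPY (chromosome 7, 24284190 to 24291862), a neuropeptide, from 24.1 ± 0.222 to 1141 ± 101 CPM (log2 change 5.50 ± 0.092). The retinoic acid-binding protein CRABP1 rose by 4.91 ± 0.079 and ID3 fell further, to 15.6 ± 2.31 CPM at day 18. HSPA5 was at 955.9 ± 33.9 CPM at day 15 and 456.7 ± 9.07 CPM at day 18.

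Of 18 neuronal cytoskeleton genes 10 rose and 1 fell at day 15 (10 and 1 adjusted over the list alone; adjusted p = 0.000224). At day 18, 10 rose and 4 fell (10 and 4 adjusted over the list alone; adjusted p = 0.00153), with the microtubule-associated protein MAPT at 2.31 ± 0.071 at day 18. Of 22 synaptic vesicle and release genes 15 rose and 1 fell at day 15 (15 and 1 adjusted over the list alone; adjusted p = 1.23e-05). At day 18, 14 rose and 4 fell (14 and 4 adjusted over the list alone; adjusted p = 0.000343). Among these, the vesicle protein SYP changed by 1.24 ± 0.066 at day 18. All 30 cell cycle genes fell at both days (30 adjusted over the list alone), with adjusted p = 1.16e-18 at day 15 and 8.02e-20 at day 18. The 12 libraries of day 18 also held keratin transcripts of basal epithelia: KRT5 was at 34.4 ± 8.34 CPM at day 18 and 0.481 ± 0.167 CPM at day 6 without Pb. Of 8 epithelial and blood cell markers 6 rose and 1 fell at day 18 (6 and 1 adjusted over the list alone; adjusted p = 0.00479), and the adjusted p = 0.0646 with an estimated correlation. At day 15, 3992 genes were higher and 4911 lower, and at day 18, in the other library pool, 4895 were higher and 5298 lower. After rescaling the balance turned, with 4494 higher and 4112 lower at day 15 and 5190 higher and 4968 lower at day 18. The plot of 6 genes over the days shows these courses.

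**Figure D1:**
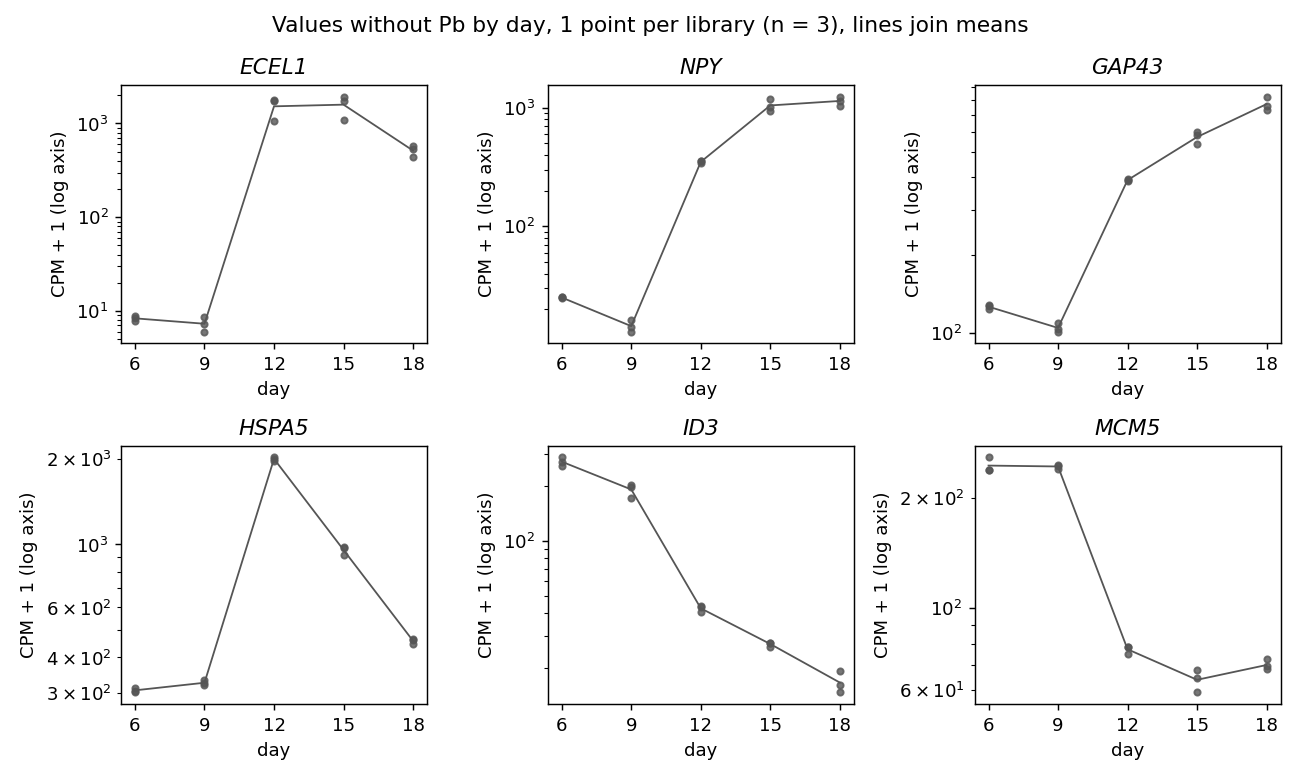
Level in CPM + 1 (log axis) of ECEL1, NPY, GAP43, HSPA5, ID3 and MCM5 at 0 µM Pb against day, with 1 point per library (3 per day) and a line through the means. ECEL1 rose to 1523 CPM at day 12, HSPA5 peaked at 2002 CPM at day 12, and ID3 fell to 15.6 CPM at day 18.

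The mean of the 5 within-day differences asks which genes differ with Pb on average over the days, and it can pass where only some days differ. At 10 µM, the stress-induced GDF15 (chromosome 19, 18386158 to 18389176) was higher by 1.11 ± 0.047 on the log2 scale (adjusted p = 3.5e-23), and COL3A1 (chromosome 2, 188974373 to 189012746), a fibrillar collagen, had a log2 change of -1.88 ± 0.10 (adjusted p = 2.61e-19). At day 12, GDF15 stood at 1188 ± 42.9, 1376 ± 56, 1795 ± 115 and 2463 ± 76.4 CPM with 0, 0.16, 1.26 and 10 µM Pb, while COL3A1 stood at 46.2 ± 0.454, 17.5 ± 1.54, 14.7 ± 0.347 and 2.20 ± 0.207 CPM. NQO1 (chromosome 16, 69709401 to 69726560) rose by 0.73 ± 0.049, the metal-binding metallothionein MT2A by 0.59 ± 0.055 and CDKN1A by 0.49 ± 0.036 at 10 µM.

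With 10 µM several lists were higher as the mean over days. In the unfolded protein response list 18 of 20 genes rose (19 adjusted over the list alone; adjusted p = 9.32e-42), with HSPA5 at 0.37 ± 0.021 and the secreted factor MANF at 0.44 ± 0.028, values that were 0.13 and 0.26 without day 18. Of 24 NRF2 targets 15 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 3.26e-13). Of 20 p53 targets 13 rose (14 adjusted over the list alone; adjusted p = 6.84e-15). Among these, ZMAT3 changed by 0.27 ± 0.029. Of 9 metallothionein and zinc transport genes 5 rose (5 adjusted over the list alone; adjusted p = 0.000178). Of 27 cholesterol and fatty acid synthesis genes 17 rose (18 adjusted over the list alone; adjusted p = 1.8e-16). Among these, HMGCS1, an early enzyme of the pathway, changed by 0.38 ± 0.040. Of 21 immediate early genes 14 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 9.72e-10), with EGR1 at 0.64 ± 0.079, or 0.34 without day 18. Of 13 mitochondrially encoded transcripts 12 rose (12 adjusted over the list alone; adjusted p = 4.2e-24). Among these, the complex I subunit ND4 changed by 0.44 ± 0.035. The heat shock list (adjusted p = 0.0864) and the ATF4 and amino acid list (adjusted p = 0.152) did not pass.

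Cell cycle, mesenchymal and noradrenergic genes were lower at 10 µM as the mean over days. Of 30 cell cycle genes 29 fell (30 adjusted over the list alone; adjusted p = 6.38e-54). Among these, MCM7 (chromosome 7, 100092728 to 100101397), a helicase subunit, changed by -0.39 ± 0.022 and RRM2, which supplies deoxynucleotides, by -0.41 ± 0.028. Of 20 mesenchymal and S-type (substrate-adherent) markers 12 fell and 2 rose (12 and 3 adjusted over the list alone; adjusted p = 7.13e-08). Among these, the intermediate filament VIM changed by -0.64 ± 0.042. Of 18 noradrenergic genes 9 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 8.17e-08), with SLC6A2 at -0.28 ± 0.035. Of 13 nuclear-retained and histone transcripts 9 fell (9 adjusted over the list alone; adjusted p = 4.96e-06). Among these, the histone gene H2AC6 changed by -0.37 ± 0.050. Of 32 ribosomal protein genes 27 fell (31 adjusted over the list alone; adjusted p = 6.99e-23), and the adjusted p = 0.05 with an estimated correlation.

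At 10 µM, 1057 genes were higher and 1241 lower as the mean over days, 2298 in all. The balance turned without day 18 (780 higher and 717 lower, 1497 in all) and after GC and length correction (1243 higher and 1182 lower). Of 28 lists, 16 passed with the preset correlation (9 higher, 7 lower) and 7 higher and 4 lower with an estimated correlation.

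The lower doses changed some of the named genes as well. COL3A1 changed by -0.69 ± 0.10 at 0.16 µM (adjusted p = 0.000194) and by -0.99 ± 0.10 at 1.26 µM (adjusted p = 5.57e-09) as the mean over days, and NQO1 was higher by 0.28 ± 0.049 (adjusted p = 0.00258) and 0.46 ± 0.049 (adjusted p = 6.6e-09). At 1.26 µM CDKN1A rose by 0.34 ± 0.036 and VIM fell by 0.36 (SE 0.042). Of 30 cell cycle genes 1 fell at 0.16 µM (4 adjusted over the list alone; adjusted p = 3.7e-13) and 25 at 1.26 µM (26 adjusted over the list alone; adjusted p = 1.51e-48). Of 20 unfolded protein response genes 3 rose at 0.16 µM (13 adjusted over the list alone; adjusted p = 7.38e-15) and 12 at 1.26 µM (16 adjusted over the list alone; adjusted p = 3.3e-15). The 3 genes at 0.16 µM, HSPA5, PDIA4 and DNAJC3 (adjusted p = 0.0418 each), lost their calls without a filter, with rescaling, with a block for the replicate number, with edgeR and without day 18. Over 9 alternatives their adjusted p ran from 0.00906 to 0.14, from 0.0218 to 0.197 and from 0.0457 to 0.453, and their calls ended in 26, 22 and 24 of 30 fits without 1 library.

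At 0.16 µM 19 genes passed, 9 higher and 10 lower, and at 1.26 µM 586, 255 higher and 331 lower. The share of higher genes was 47.4% at 0.16 µM, with 35.7% after rescaling, 57.6% after GC and length correction, 61.9% in a fit of only the groups compared and 69.6% without the 2 libraries low in long transcripts. It was 43.5% at 1.26 µM and 29% with edgeR. The 0.16 µM count was 12 without replicate 1 or 2 of day 6 at 0 µM, replicate 1 of day 12 at 0 µM, or replicate 1 or 3 of day 12 at 0.16 µM. It was 11 without replicate 2 of day 9 at 0 µM, or replicate 1 of day 9, 2 of day 12 or 1 of day 18 at 0.16 µM. It was 10 without replicate 3 of day 6 at 0 µM, or replicate 2 of day 9 or 1 or 2 of day 15 at 0.16 µM. It was 9 without replicate 2 of day 6 at 0.16 µM, 8 without replicate 1 of day 15 at 0 µM, 100 without replicate 3 of day 18 at 0 µM, and 5 without day 18. The 1.26 µM count was 1175 without replicate 3 of day 18 at 0 µM and 247 without day 18.

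The dose trend asks which genes follow the dose steps. Per step, GDF15 rose by 0.35 ± 0.015 on the log2 scale (adjusted p = 3.16e-23), NQO1 by 0.24 ± 0.015 (adjusted p = 1.19e-16) and the metallothionein MT1F by 0.20 ± 0.022, while COL3A1 fell by 0.59 (SE 0.032, adjusted p = 1.93e-19) and LAYN, a hyaluronan receptor, by 0.31 (SE 0.023). All 30 cell cycle genes had a falling slope (30 adjusted over the list alone; adjusted p = 1.37e-56), and 18 of 20 unfolded protein response genes had a rising slope (19 adjusted over the list alone; adjusted p = 4.45e-39). With the slope, 1108 genes were higher and 1281 lower with dose, a balance that turned without day 18 (852 and 791) and after GC and length correction (1286 and 1221).

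**Figure D2:**
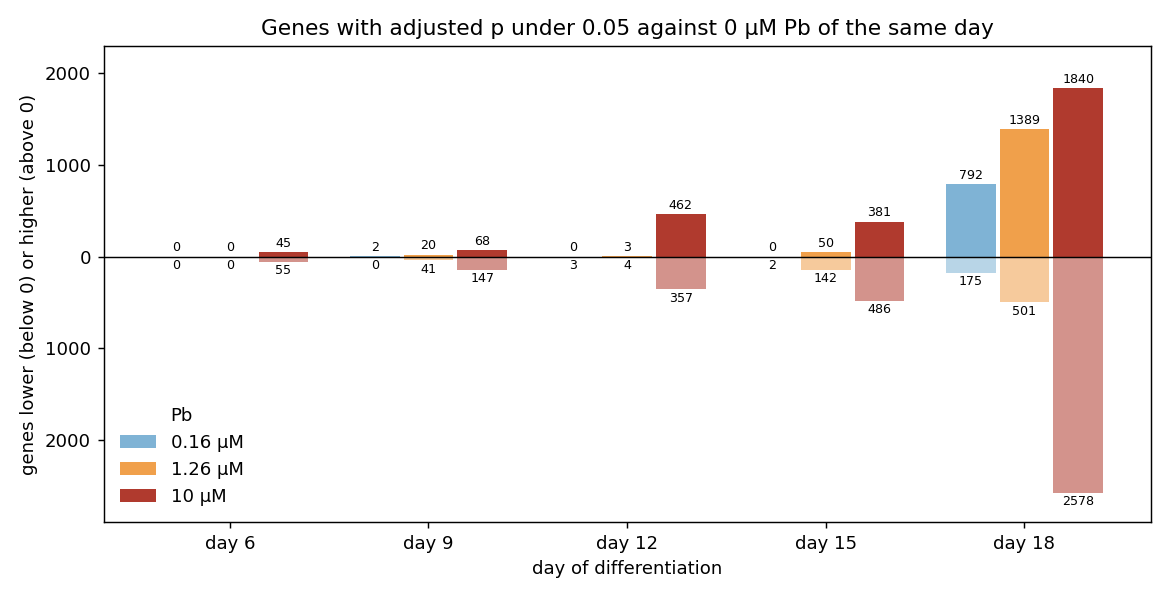
Number of genes higher (upward bars) and lower (downward bars) with each Pb dose than with 0 µM at each day, at adjusted p below 0.05. The largest count was at day 18 with 10 µM, 1840 higher and 2578 lower.

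The comparisons within each day ask when the differences arise. At day 6, after 1 day of exposure, 10 µM raised NQO1 from 16.4 ± 1.38 to 31.6 ± 6.21 CPM (log2 change 0.89 ± 0.11, adjusted p = 1.87e-06) and the chaperone genes HSPA5, by 0.36 ± 0.047, and CALR, by 0.38 ± 0.048. SPOCK1, a secreted proteoglycan, went from 16.3 ± 2.51 to 7.74 ± 0.626 CPM. Of 20 unfolded protein response genes 9 rose (12 and 1 fell adjusted over the list alone; adjusted p = 2.71e-17). Of 24 NRF2 targets 4 rose (5 adjusted over the list alone; adjusted p = 2.71e-10). No gene passed in the main limma fit at 0.16 µM (937 at an unadjusted p under 0.05, 3 by edgeR) or at 1.26 µM (1254 at an unadjusted p under 0.05, 0 by edgeR), where MT1F had a log2 difference of 0.71 ± 0.16 (adjusted p = 0.126). At 0.16 µM limma called 12 genes without a filter, 3 with rescaling and 3 with a block for the replicate number. It called 5 there after GC and length correction and 7 without the libraries low in long transcripts. At 1.26 µM it called 5 without a filter.

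At 10 µM and day 6, 45 genes were higher and 55 lower. The share of higher genes was 53.5% after rescaling and 60% without a filter. The count was 31 and 48 without replicates 1 and 2 at 0 µM, 1061 and 389 without replicates 1 and 2 at 10 µM, 20 without replicate 3 at 10 µM, the library low in long transcripts, and 23 without both such libraries. In a fit of day 6 alone it was 0 with limma (1335 at an unadjusted p under 0.05, and 89 by edgeR on all libraries), where NQO1, HSPA5, CALR and SPOCK1 each had an adjusted p of 0.245 (over 8 alternatives from 1.44e-06 to 0.245 for NQO1 and HSPA5, and from 1.49e-06 to 0.245 for CALR and SPOCK1). Without 1 library, the 0.16 µM count at day 6 was 1 (replicate 2 at 0 µM), 6 (replicate 3 at 0 µM) or 8 (replicate 1 at 0.16 µM), and the 1.26 µM count was 1 (replicate 1 at 0 µM), 3 (replicate 1 at 1.26 µM) or 8 (replicate 3 at 1.26 µM).

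At day 9 the heme-degrading enzyme gene HMOX1 (chromosome 22, 35381096 to 35394207) was at 1.41 ± 0.623 CPM without Pb and at 8.03 ± 0.745, 7.06 ± 0.941 and 3.17 ± 1.1 CPM with 0.16, 1.26 and 10 µM. It and NQO1 were the 2 genes that passed at 0.16 µM, with log2 changes of 1.94 ± 0.16 (adjusted p = 1.35e-11) and 0.81 ± 0.11 (adjusted p = 1.34e-05), and both also rose at 1.26 µM. With 10 µM the keratin KRT18 went from 18.1 ± 1.28 to 3.46 ± 0.34 CPM (log2 change -2.10 ± 0.14, adjusted p = 5.14e-15). The membrane-binding annexin ANXA2 changed by -1.54 ± 0.10 and VIM by -1.26 ± 0.093. Of 8 epithelial and blood cell markers 2 fell, the keratins KRT18 and KRT8 (2 adjusted over the list alone; adjusted p = 0.00115). Of 20 mesenchymal markers 6 fell (9 adjusted over the list alone; adjusted p = 2.15e-17). Of 20 p53 targets 5 rose (10 adjusted over the list alone; adjusted p = 1.29e-15), with GDF15 at 1.05 ± 0.11.

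At day 9 with 10 µM 68 genes were higher and 147 lower, and the count of 215 was 141 without replicate 1 at 10 µM. With 1.26 µM 20 were higher and 41 lower, and the count of 61 was 32 without replicate 3 at 0 µM, 22 without replicate 3 at 1.26 µM and 17 in a fit of day 9 alone.

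At day 12 COL3A1 was lower at every dose, with log2 changes of -1.36 ± 0.23 at 0.16 µM (adjusted p = 0.00256), -1.58 ± 0.23 at 1.26 µM (adjusted p = 5.88e-05) and -3.88 ± 0.23 at 10 µM (adjusted p = 1.37e-17). TWIST2, a mesenchymal transcription factor, went from 10.7 ± 1.26 CPM without Pb to 4.44 ± 0.353, 4.13 ± 0.681 and 1.22 ± 0.563 CPM. TSC22D1, a leucine zipper regulator, passed at 0.16 µM together with COL3A1 and TWIST2, at -0.28 ± 0.046 (adjusted p = 0.00256). CDKN1A rose by 0.59 ± 0.080 at 1.26 µM and by 0.74 ± 0.080 at 10 µM (adjusted p = 8.24e-09). Of 20 p53 targets 11 rose at 10 µM (15 adjusted over the list alone; adjusted p = 1.55e-18). Among these, BAX, which promotes apoptosis, changed by 0.50 ± 0.071. Of the mesenchymal markers, 9 of 20 fell and 1 rose (9 and 2 adjusted over the list alone; adjusted p = 3.99e-09). The calls of TWIST2 at 0.16 and 1.26 µM ended with a pseudocount of 0.25 and with edgeR (edgeR adjusted p = 0.537 at 0.16 µM, over 8 alternatives from 0.00216 to 0.537, and 0.281 at 1.26 µM, from 0.000449 to 0.281). Those at 0.16 µM ended without replicate 2 at 0 µM (adjusted p of 0.0516 for TSC22D1 and between that and 0.0818 for TWIST2) and without replicate 1 at 0.16 µM (0.0818 for both). In a fit of day 12 alone TSC22D1 had 0.0674 and TWIST2 0.065 at 0.16 µM (TSC22D1 over 8 alternatives from 0.000999 to 0.0674).

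At day 12 with 10 µM 462 genes were higher and 357 lower, 56.4% higher as deposited and 46.2% after rescaling. The count of 819 was 463 and 438 without replicates 2 and 3 at 0 µM and 446 and 463 without replicates 2 and 3 at 10 µM. With 1.26 µM 3 genes were higher and 4 lower (42.9% higher, 30% after rescaling), 11 in all without replicate 2 at 1.26 µM. With 0.16 µM 3 genes were lower, and 1 without replicate 2 at 0 µM or without replicate 1 at 0.16 µM.

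At day 15 TFPI2 was at 1125 ± 54.9 CPM without Pb and 2222 ± 41.5 CPM with 10 µM (log2 change 0.98 ± 0.076, adjusted p = 1.12e-12), and GDF15 was higher by 1.13 ± 0.11. COL3A1 had log2 changes of -1.58 (SE 0.23, adjusted p = 0.000136) at 0.16 µM, -1.76 at 1.26 µM and -2.12 at 10 µM. CDC20, which drives the exit from mitosis, fell by 0.63 (SE 0.070) at 1.26 µM and by 0.68 (SE 0.070) at 10 µM. Of 30 cell cycle genes 23 fell at 10 µM (27 adjusted over the list alone; adjusted p = 7.34e-48). Of 32 ribosomal protein genes 30 fell (32 adjusted over the list alone; adjusted p = 1.88e-46). Of 20 unfolded protein response genes 14 rose (17 adjusted over the list alone; adjusted p = 7.84e-20), and HSPA5 was also higher at 1.26 µM by 0.32 ± 0.047.

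At day 15 with 10 µM 381 genes were higher and 486 lower, 43.9% higher as deposited and 30.8% after rescaling, and 52.6% in a fit of day 15 alone. The count of 867 was 490 without replicate 3 at 0 µM and 468 without replicate 2 at 10 µM. With 1.26 µM 50 were higher and 142 lower. The count of 192 was 68 and 99 without replicates 1 and 3 at 0 µM, 90 and 65 without replicates 2 and 3 at 1.26 µM, 303 without the libraries low in long transcripts and 45 in a fit of day 15 alone. With 0.16 µM COL3A1 and TSC22D1 were the 2 genes that passed, TSC22D1 at -0.24 ± 0.046 (adjusted p = 0.0442). The count was 1 without replicate 1 or 2 at 0 µM or at 0.16 µM, where TSC22D1 had adjusted p-values of 0.788, 0.537, 0.539 and 0.663 in that order. Its call also ended with a block for the replicate number (adjusted p = 0.261), after GC and length correction (0.144) and in a fit of day 15 alone (0.609), over 8 alternatives from 0.00607 to 0.609.

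At day 18 unfolded protein response genes were higher and cell cycle genes lower with 10 µM. HSPA5 was at 456.7 ± 9.07 CPM without Pb and 1127 ± 58.9 CPM with 10 µM (log2 change 1.30 ± 0.047, adjusted p = 2.47e-26). Of the unfolded protein response genes 19 of 20 rose (19 adjusted over the list alone; adjusted p = 9e-45). MCM7 went from 278.5 ± 20.6 to 150.4 ± 7.21 CPM (log2 change -0.88 ± 0.049, adjusted p = 1.48e-19). In all, 28 of 30 cell cycle genes fell (28 adjusted over the list alone; adjusted p = 7.94e-31). STC1, a secreted glycoprotein, went from 0.289 ± 0.104 to 4.95 ± 0.259 CPM, and GFRA2, a receptor for the trophic factor neurturin, from 35.2 ± 5.98 to 9.36 ± 0.804 CPM. All 13 nuclear-retained and histone transcripts fell (13 adjusted over the list alone; adjusted p = 6.24e-09). All 32 ribosomal protein genes fell (32 adjusted over the list alone; adjusted p = 5.64e-20), with an adjusted p = 0.094 with an estimated correlation for the latter.

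At day 18 with 10 µM 1840 genes were higher and 2578 lower, 41.6% higher as deposited and 55.5% after rescaling. The count of 4418 was 2769 without replicate 1 at 0 µM, the library low in long transcripts, and 2657 in a fit of day 18 alone. The cadherin CDH11, at 49.7 ± 10.5 CPM without Pb, was at 83.3 ± 4.93 CPM with 0.16 µM (log2 change 0.75 ± 0.11, adjusted p = 0.000159) and at 87 ± 7.71 CPM with 1.26 µM (log2 change 0.81 ± 0.11, adjusted p = 2.38e-05). FANCD2, a DNA repair gene, fell by 0.58 (SE 0.087) at 1.26 µM. In a fit of day 18 alone no gene passed with limma at 0.16 or 1.26 µM, against 2363 and 3120 at an unadjusted p under 0.05 and 796 and 1834 by edgeR on all libraries (CDH11, adjusted p = 0.206 and 0.0654, over 8 alternatives from 7.15e-06 to 0.206 and from 1.07e-06 to 0.0654, and FANCD2 0.0835, from 5.33e-06 to 0.0835). With all libraries 792 genes were higher and 175 lower at 0.16 µM, and 1389 higher and 501 lower at 1.26 µM. After GC and length correction 451 were higher and 291 lower at 0.16 µM, and 976 higher and 652 lower at 1.26 µM. The 0.16 µM count of 967 was 4 and 2481 without replicates 1 and 3 at 0 µM, 159 and 35 without replicates 1 and 2 at 0.16 µM and 117 without the libraries low in long transcripts. The 1.26 µM count of 1890 was 76 and 3018 without replicates 1 and 3 at 0 µM, 1223 without replicate 2 at 1.26 µM and 583 without the libraries low in long transcripts.

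**Figure D3:**
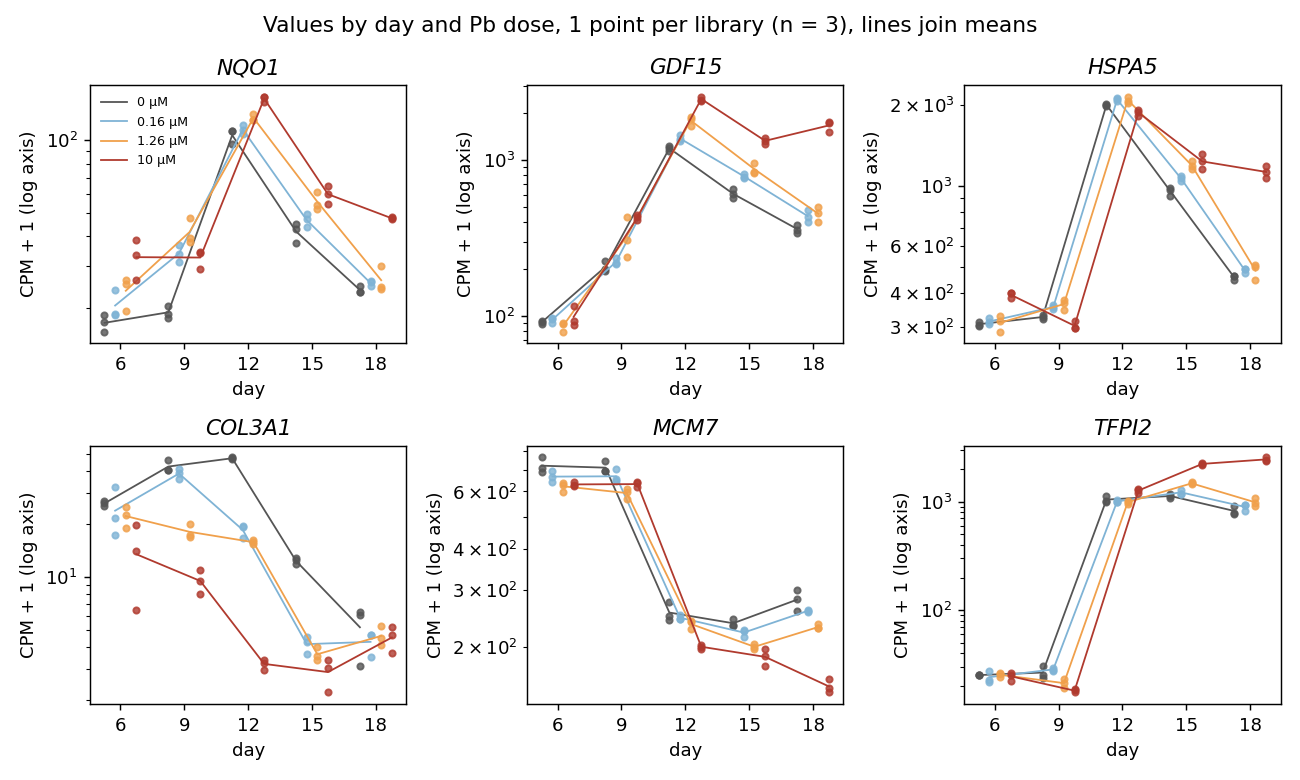
Level in CPM + 1 (log axis) of NQO1, GDF15, HSPA5, COL3A1, MCM7 and TFPI2 against day for 0, 0.16, 1.26 and 10 µM Pb, with 1 point per library and lines through the group means. At day 18, GDF15 was at 360.2 CPM without Pb and at 1667 CPM with 10 µM.

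The tests of Pb by day ask whether the Pb differences change over the course. Exposure began at day 5 in every group with Pb. The day of differentiation and the length of exposure hence cannot be told apart. With 10 µM HSPA5 had log2 differences of 0.36, -0.11, -0.09, 0.37 and 1.30 at days 6, 9, 12, 15 and 18 (adjusted p = 1.14e-21). TFPI2 had differences of -0.04, -0.54, 0.28, 0.98 and 1.58 (adjusted p = 5.94e-20) and PDIA4 of 0.22, -0.06, -0.07, 0.31 and 1.13 (adjusted p = 1.59e-19). STC1, whose group means at days 6 and 9 were all under the 3-read floor, had an adjusted p of 3.17e-17 with limma but 0.266 with edgeR (over 9 alternatives from 1.02e-18 to 0.266). The 10 µM test passed for 3308 genes, and the joint test of all doses for 1806 genes. The joint test spreads over 12 contrasts, so it can miss genes that vary at 10 µM alone. These counts were 825 and 419 without day 18, the 10 µM count was 2008 in a fit of 0 and 10 µM alone, and the count of the joint test was 2956 without replicate 3 of day 18 at 0 µM.

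Across all 15263 genes, the 10 µM differences of different days resembled each other weakly, with a mean Pearson r of 0.123 over 10 pairs of days, 8 of them positive (exact permutation p = 0.019). The mean r was 0.08 at 1.26 µM (exact permutation p = 0.047) and 0.043 at 0.16 µM (exact permutation p = 0.25), each from 3200000 relabellings whose smallest possible p is 6.3e-07. These correlations are across genes, which are not independent replicates. Among genes with a mean of at least 10 CPM the p-values were 0.087 at 10 µM and 0.093 at 1.26 µM, and the 1.26 µM value was 0.14 without day 18. The map of lists by day shows the differences of the groups at 10 µM.

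**Figure D4:**
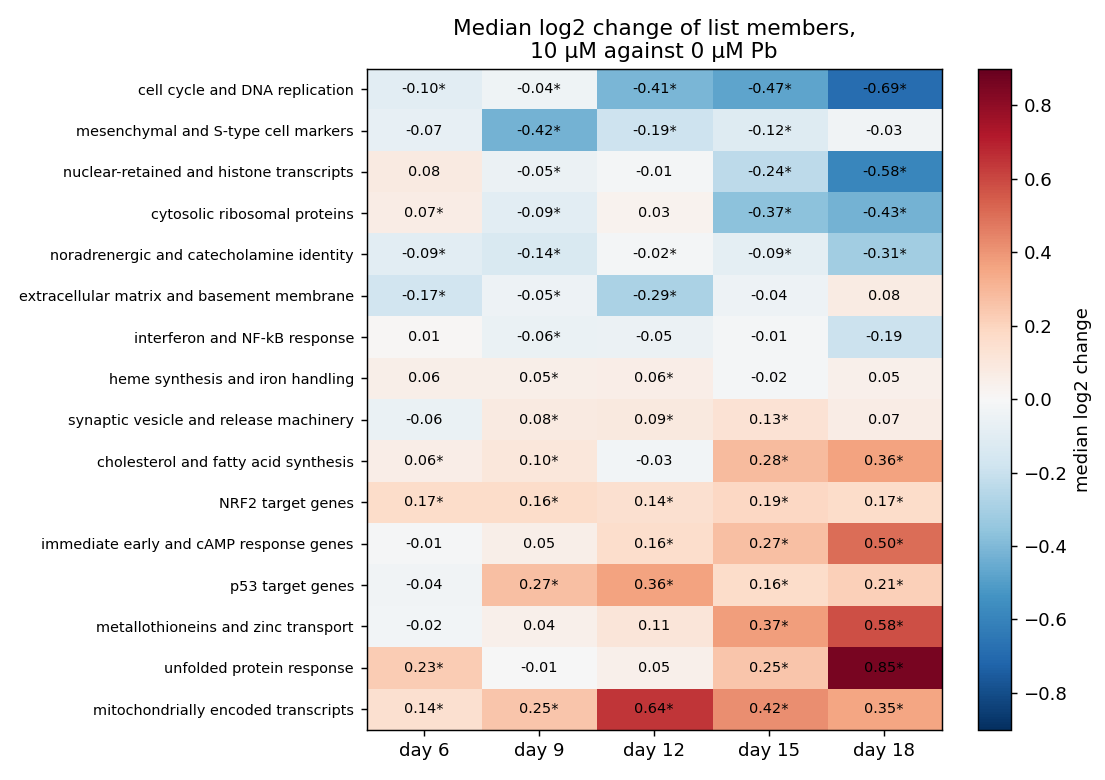
Median log2 change of the members of 16 gene lists, 10 µM against 0 µM Pb, at each day (colour scale), with an asterisk where the list test passed at an adjusted p below 0.05. At day 18 the cell cycle list had the lowest median of the lists shown and the unfolded protein response list the highest.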

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

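The tests weighing the explanations of 3 patterns below, and the counts over other splits of the libraries, were chosen only after the results were seen, and the tests of Pb by day were planned.

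With 10 µM Pb the difference from 0 µM varied between days, by a test of the difference itself. The chaperone gene HSPA5 was higher at days 6, 15 and 18 with log2 differences of 0.36, 0.37 and 1.30, and had -0.11 and -0.09 at days 9 and 12. COL3A1, a collagen gene, had log2 differences of -1.10, -2.17, -3.88, -2.12 and -0.14 at days 6, 9, 12, 15 and 18. Its level without Pb ran from 45.81 to 46.69 CPM at day 12, from 10.77 to 11.76 CPM at day 15 and from 2.132 to 5.303 CPM at day 18. A large fall could hence not show at day 18 for COL3A1. The 10 µM test passed for 3308 of 15263 genes and the joint test of all doses for 1806 genes (825 and 419 without day 18). The genes listed next are those named for Pb that passed the 10 µM test. Since genes were named partly for a small p at single days or in this test, their number says nothing about genes in general.

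The adjusted p-values were, in increasing order, HSPA5 1.14e-21, TFPI2 5.94e-20, PDIA4 1.59e-19, STC1 3.17e-17, CALR 6.46e-16, SCG2 7.84e-16, ANXA2 5.35e-15, CDH11 7.97e-14, MCM5 2e-13, GDF15 4.06e-13, GFRA2 2.45e-12, MANF 2.59e-12, COL3A1 2.27e-11, DNAJC3 2.37e-11 and TSC22D1 4.72e-11. Then came MCM7 7.02e-11, KRT18 1.23e-10, SPRY4 3.84e-10, RRM2 6.48e-10, TWIST2 1.79e-09, ISOC1 4.37e-09, TAC1 7.31e-09, FANCD2 1.29e-08, FAM30A 2.11e-08, EPAS1 3.06e-08, ATAD5 3.85e-08, UBE2C 4.07e-08, SYT7 4.64e-08, PCLAF 5.07e-08 and RPL4 5.07e-08. The next values were TFAP2B 7.2e-08, SERPINF1 1.28e-07, ENPP2 1.39e-07, VIM 3.15e-07, BIRC5 3.49e-07, TGM2 3.62e-07, ATF4 5.22e-07, HSPA6 5.38e-07, STMN4 8.12e-07, EGR1 8.12e-07, DPF3 9.03e-07, RPLP0 9.18e-07, CCL2 9.43e-07, NFASC 9.63e-07 and DUSP4 1.18e-06. These were followed by RPL5 1.55e-06, IL32 3e-06, SPOCK1 3.19e-06, CD44 4.76e-06, CCN1 8.93e-06, SQLE 9.09e-06, APLNR 1.01e-05, CPA4 1.98e-05, NAP1L1 2.57e-05, H2AZ1 2.64e-05, HMGCS1 2.76e-05, RTL1 3.19e-05, CDKN1A 3.33e-05, CAVIN1 4.26e-05 and MT2A 4.3e-05. Larger values were those of LAYN 4.51e-05, KRT86 0.00012, GPX3 0.000197, ND5 0.000219, H4C3 0.000273, CDC20 0.000359, CXCL8 0.000531, H2AC6 0.000637, ND4 0.000709, ICAM1 0.000792, COL17A1 0.00106, PCDH12 0.0013, CHAC1 0.0025, KITLG 0.00254 and HMOX1 0.00279. The remaining values were those of BAX 0.00349, PHLDB2 0.00445, PPP1R15A 0.0071, MSMO1 0.00934, HRH1 0.00975, GATA2 0.0106, COX2 0.0106, BCL11A 0.0112, SMOC1 0.0253, NQO1 0.0373, CREM 0.0394, PDE2A 0.0424 and EDA2R 0.0487. In this list COX2, ND4 and ND5 are mitochondrially encoded transcripts. Because day 18 is alone in its library pool, a difference between day 18 and the other days cannot be told apart from a difference between pools. The day of differentiation and the length of exposure to Pb cannot be told apart either.

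At day 18, 792 genes were higher and 175 lower with 0.16 µM Pb than with 0 µM, and 1389 higher and 501 lower with 1.26 µM. The single 0 µM library low in long transcripts stays open as an explanation. Without it (replicate 1) the count at 0.16 µM was 4, against 941 and 2481 without replicates 2 and 3 at 0 µM. The slopes with length of replicates 1 to 3 at 0 µM were -0.503, -0.169 and 0.008. Replicate 2 hence leaned the same way, less strongly, and only replicate 3 did not. The count was also 159 and 35 without replicates 1 and 2 at 0.16 µM, and changed by less than 1.5 times without replicate 3. The slopes with length of the 3 libraries at 0.16 µM were 0.078, 0.107 and 0.035, so the 2 falls do not weigh against a part of length. At 1.26 µM the count was 76 without replicate 1 at 0 µM, 1851 and 3018 without replicates 2 and 3 at 0 µM and 1223 without replicate 2 at 1.26 µM. It changed by less than 1.5 times without replicate 1 or 3 at 1.26 µM. There the slopes of replicates 1 to 3 were 0.121, 0.109 and 0.095, an order that the counts did not follow. Without both libraries low in long transcripts the counts were 117 and 583. The gene CDH11 passed also without replicate 1 at 0 µM, with log2 changes of 0.57 at 0.16 µM (adjusted p = 0.0186, over 8 other alternatives from 7.15e-06 to 0.206) and 0.63 at 1.26 µM (adjusted p = 0.00218, over 8 others from 1.07e-06 to 0.0654). Its call hence did not rest on that library alone. Replicate 2 at 0 µM stayed in that fit, so a part of length is not excluded for CDH11. A trend with GC content and length stays open too: after correction 451 genes were higher and 291 lower at 0.16 µM, and 976 and 652 at 1.26 µM, so the excess of higher genes became smaller and did not end. An effect of Pb at 0.16 µM stays open, because after the correction the differences of days 15 and 18 had a Pearson r of 0.131 across genes (exact permutation p = 0.17, 400 relabellings, smallest possible p 0.005), and at 1.26 µM 0.263 (exact permutation p = 0.09).

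Transcripts of basal epithelial cells were present in the 12 libraries of day 18, where KRT5 ran from 28.1 to 44 CPM, and its highest value elsewhere was 1.08 CPM. Of 18 basal epithelial markers, 15 were higher in every library of day 18 than in every other library. All 48 libraries of days 6 to 15 held KRT5 reads. The means of KRT5, KRT14, KRT17 and KRT6A over days 6 to 15 were 1.76%, 1.72%, 1.61% and 1.63% of those of day 18. Over the 18 markers this share ran from 1.43% (KRT6B) to 91.5% (KRT15). The source stays open. The sum of KRT5, KRT14, KRT17 and KRT6A varied by a factor of 1.64 among the 12 libraries, which allows reads carried over from other samples of the pool as well as epithelial cells at a like share in each dish. These cannot be told apart, since day 18 is the only day of its pool.

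COL3A1 was lower with Pb at day 12. A loss of fibroblasts rich in COL1A2 is argued against, as COL1A2 was at 0.393 CPM without Pb where COL3A1 was at 46.2 CPM. A single library is argued against too: without any 1 of the 6 libraries the 10 µM log2 change lay between -3.92 and -3.83 (highest adjusted p = 4.18e-15). A smaller share of substrate-adherent cells stays open, since 9 of 20 mesenchymal markers fell, 1 rose and no count of cells was available. An effect of Pb on the gene itself stays open and untested.

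Other splits of the libraries were counted for the numbers of genes past the threshold. For the Pb means over days, the dose trend and the tests of Pb by day, 1 of 100 splits, the real one, gave as many genes. This is the smallest share that 100 splits can give, so it argues against chance without excluding it. For Pb by day, the drawn splits mix the doses within each day. They hence cannot test a Pb difference that stays the same over the days. The real and the highest other counts were 19 and 1 at 0.16 µM, 586 and 183 at 1.26 µM, 2298 and 724 at 10 µM, 2389 and 2 for the trend, 1806 and 495 for Pb by day with all doses jointly, and 3308 and 2500 for Pb by day at 10 µM. A drawn split can keep the real groups at some of the days.

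For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Against day 6, the real and highest other counts were 785 and 1 at day 9, 8583 and 0 at day 12, 8903 and 0 at day 15, and 10193 and 669 at day 18. At 0.16 µM they were 0 and 1, 2 and 1, 3 and 0, 2 and 0, and 967 and 932 from day 6 to day 18. At 1.26 µM they were 0 and 4, 61 and 1, 7 and 0, 192 and 1, and 1890 and 1434, and at 10 µM 100 and 13, 215 and 0, 819 and 1, 867 and 0, and 4418 and 982.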

How the results depend on the processing

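Leaving out the 2 libraries low in long transcripts and the GC and length correction were tests chosen only after the results were seen, and the other alternatives were planned. Unless a cause is given, the cause was not tested.

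Of the results for named genes and lists, the direction and the side of the threshold were the same in 483 of 488 with a pseudocount of 0.25, 299 of 313 without a filter, 475 of 488 with rescaling, 262 of 293 in a fit of only the groups compared, 477 of 488 with a block for the replicate number, 301 of 313 with edgeR, 474 of 488 without the 2 libraries, 453 of 473 after GC and length correction, 80 of 94 without day 18, 16 of 16 with a linear dose, and 107 of 175 with an estimated correlation. With each replicate left out it was 4512 of 4734. Genes were named, and lists entered, mostly because they passed in the main fit. High shares were hence likely in advance and say little about results in general. The list of cytosolic ribosomal proteins at 10 µM and day 6 reversed against other genes without the 2 libraries, at a median of 0.00997 (adjusted p = 0.953), and the cause was not tested.

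A fit of only the groups compared has fewer libraries to estimate the spread, and it uses the spread of those libraries alone. The main fit shares 1 estimate over 20 groups, so its p-values can be too small where replicates differ more. Chi-square per degree of freedom between replicates reached 45.3 at day 6 with 10 µM and 36.8 at day 18 with 0 µM. The number of libraries and their own spread were not told apart. At 10 µM and day 12 the count rose, from 819 to 1120 in a fit of day 12 alone. Such fits gave 422 genes at day 9 against day 6, 1 and 0 at 0.16 µM at days 15 and 18, 17, 45 and 0 at 1.26 µM at days 9, 15 and 18, 0 and 2657 at 10 µM at days 6 and 18, 362 for the 1.26 µM mean and 2008 for Pb by day at 10 µM. Without day 18, the day with the most genes past the threshold at each dose, the means at 0.16, 1.26 and 10 µM gave 5, 247 and 1497 genes, and the tests of Pb by day 419 (all doses jointly) and 825 (10 µM). Fewer samples and the loss of that day's differences were not told apart.

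Without a filter the 0.16 µM counts were 12, 15, 7, 13 and 610 at days 6, 9, 12, 15 and 18 and 10 for the mean, and the 1.26 µM counts 5 and 19 at days 6 and 12. At 0.16 µM rescaling gave 3 and 16 at days 6 and 12, edgeR 3 and 7, and the replicate block 3, 5 and 1 at days 6, 12 and 15. The cause was not tested.

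Without the 2 libraries low in long transcripts the counts were 7, 6 and 117 at 0.16 µM at days 6, 12 and 18 and 46 for the mean, 12, 303 and 583 at 1.26 µM at days 12, 15 and 18, and 23 at 10 µM at day 6. After GC and length correction they were 5 and 7 at 0.16 µM at days 6 and 12 and 33 for the mean, 13 at 1.26 µM at day 12 and 62 at 10 µM at day 6, where 6 lists were called. The cause was not tested.

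With an estimated correlation the lists called were 7, 9, 8 and 7 at days 9, 12, 15 and 18 against day 6 (13, 14, 13 and 14 with the preset one), 4 for the 0.16 µM mean (10), and 2, 7 and 7 at 10 µM at days 6, 9 and 12 (10, 15 and 13). The similarity of days at 10 µM was 0.129 (exact permutation p = 0.087) among genes with at least 10 CPM, and at 1.26 µM 0.105 (p = 0.093) among these genes and 0.065 (p = 0.14) without day 18.

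With 1 replicate left out, leaving 2 against 3 libraries, the counts ran from 475 to 749 at day 9, 7718 to 8019 at day 12, 7981 to 8330 at day 15 and 9464 to 10046 at day 18 against day 6. At 0.16 µM they ran from 0 to 8, 2 to 2, 1 to 4, 1 to 3 and 4 to 2481 from day 6 to day 18, at 1.26 µM from 0 to 8, 22 to 66, 6 to 11, 65 to 220 and 76 to 3018, and at 10 µM from 20 to 1061, 141 to 190, 438 to 656, 468 to 735 and 2769 to 5036. The means ran from 8 to 100, 461 to 1175 and 2115 to 2695, the trend from 2246 to 2825, and Pb by day from 1300 to 2956 (all doses jointly) and 2422 to 4271 (10 µM). The filter at 1 CPM in at least 3 libraries set which genes were tested, above the 0.0594 to 0.181 CPM of 3 reads.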

Other observations

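The comparison of HMOX1 between doses was a test chosen only after the results were seen, and the gene lists were planned.

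At day 12 with 10 µM Pb genes of the amino acid response were higher. The transcription factor ATF4, which drives amino acid supply under stress, was at 90.02 ± 2.36 CPM (SD, n = 3) without Pb and 132 ± 6.46 CPM with 10 µM (log2 change 0.54 ± 0.074, SE, adjusted p = 1.39e-06), and CHAC1, a glutathione-degrading enzyme, was at 6.47 ± 0.858 and 12.6 ± 0.39 CPM. Of 24 genes of this list 11 rose (15 adjusted over the list alone; adjusted p = 5.9e-12).

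At day 9 with 10 µM Pb genes of the interferon and NF-kB response were lower. The chemokine CCL2 was at 21.6 ± 1.42 CPM without Pb and 4.95 ± 1.58 CPM with 10 µM, and the adhesion molecule ICAM1 at 7.23 ± 1.19 and 2.39 ± 0.692 CPM. Of 18 genes of this list 4 fell (4 fell and 1 rose adjusted over the list alone; adjusted p = 4.93e-05), CCL2, ICAM1, CXCL8 and BIRC3. The call of CXCL8 ended with a pseudocount of 0.25 (adjusted p = 0.0646), in a fit of day 9 alone (0.0588), with edgeR (0.299, over 8 alternatives from 0.000812 to 0.299) and without replicate 1 at 10 µM (0.0514). In the same comparison 6 of 20 mesenchymal markers fell (9 adjusted over the list alone; adjusted p = 2.15e-17), among them VIM by a log2 change of -1.26 and COL3A1 by -2.17.

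HMOX1 at day 9 did not follow the order of the doses. It was lower with 10 than with 0.16 µM by a log2 change of -1.15 ± 0.16 (adjusted p = 2.18e-06), in a comparison that called 177 genes, and NQO1 had -0.06 ± 0.11 (adjusted p = 1).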
